A study of Mus musculus with 2 samples.

How the data were processed

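Long-read RNA sequencing was run on adrenal glands of female mice aged 2 months of the cross named B6CASTF1/J in the labels, with total RNA given as the starting material. The 2 libraries form 1 group and are biological replicates 1 and 2 per the labels. The biosample labels number the animals 3 and 4, whereas both library labels carry the number 3, and the same donor identifier is given for both. An input of 1 µg RNA is given for replicate 1 only. P-values therefore measure the difference between these 2 libraries, which may be technical.

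The authors deposited, per library, a table of read counts per transcript model and the matching transcript models. Per the deposited readme files, the counts derive from a filtered alignment file of the same library, on mouse genome build mm10 with the GENCODE M21 annotation. Per the labels' protocols, version 3.0 of an ENCODE long-read analysis document was followed. New models carry the source TALON in the deposited files. The version of TALON, the sequencing platform and the aligner are not given in the sources used here. The deposited counts are whole numbers that were not normalised. All 141862 annotated models in both deposited files had the same exons as the M21 reference used here.

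Each model carries a class given by the authors. Annotated models match M21, and incomplete splice matches hold part of an annotated chain of introns. Models that are new in catalog or new not in catalog have a chain of introns absent from M21, and genomic models fit none of these. New genes are antisense to an annotated gene or intergenic. A check against M21 found a splice site outside the annotation in 100% of models of the class new not in catalog. The same was true of 17.1% of models new in catalog in replicate 1 and 12.3% in replicate 2.

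Counts were summed per annotated gene over all classes. Counts were scaled as CPM over reads of annotated nuclear genes, without spike-ins, genes of the mitochondrial chromosome and new genes. These totals were 1209457 reads in replicate 1 and 502655 in replicate 2. A gene was detected with at least 3 reads in each library. A count of 0 allows up to 2.48 CPM in replicate 1 and 5.97 CPM in replicate 2, taking 3 counts as the floor in each library. Intervals for shares are exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only.

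Replicate 2 was compared with replicate 1 by a two-sided Fisher's exact test per gene on the 10170 genes with at least 10 reads over both libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of at least 2-fold. Log2 ratios used 0.5 added reads, and their standard errors (SE) cover counting only. A gene list was described by the median log2 ratio of its tested members and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with under 3 tested genes received no percentile. No paired analysis and no test between groups was made, because there is 1 group.

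New transcripts were matched between the libraries by chromosome, strand and intron coordinates, and counted as shared with at least 3 reads in both. The main transcript of a gene was the most abundant over both libraries among annotated and new spliced models, in genes with at least 50 reads in each library. Its share was compared by a two-sided Fisher's exact test, with a call at an adjusted p under 0.05 and a difference of at least 10 percentage points.

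On simulated counts for 10168 genes, the per-gene test called 34.8% of 3-fold changes in genes with 10 to 99 reads and 96.3% in genes with 100 reads or more. It called 4 of 9979 unchanged genes. The test of transcript shares, on 2000 simulated genes, called 92.5% of shifts of 25 percentage points and 6 of 1800 unchanged genes. These rates describe the simulated genes only. Whether they hold for the 1887 genes of the data, with a median main transcript share of 93.0%, was not tested. The simulation held counting error only.

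The 22 gene lists, the tests with their thresholds and the rule for named genes were fixed before the data were examined. The numbers of bins and the count of lists outside the central 95% of random lists were chosen after. Named genes were drawn from the 20 nuclear genes with the highest mean CPM, the 4 most abundant members of each list, and every member of the steroidogenesis, X-zone and sex label lists. They were also drawn from the 10 largest and 10 smallest log2 ratios among called genes, the 10 most abundant shared new transcripts and the 10 largest called differences in main transcript share. For steroidogenesis, medulla, cholesterol supply and imprinted genes, they were drawn from the 4 members with the lowest main transcript share. Other named genes were chosen after their values were seen.

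The alternatives covered scaling by TMM (edgeR 4.0.16) and by median of ratios (DESeq2 1.42.0), read minimums, added reads, thinning of the deeper library in 1 random draw, transcript classes, and leaving out each replicate. Removing the trend with transcript length and GC content, and matching random lists on both, were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.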

Results

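RNA of adrenal glands of female B6CASTF1/J mice was read as long molecules in 2 libraries of 1 group. Replicate 1 held 1277310 reads and replicate 2 held 520388. Reads of annotated nuclear genes made up 94.7% and 96.6% of these. The labels give no second condition, so the data describe which genes and transcripts the gland expressed and how closely the libraries matched. Values are means ± SD (n = 2) unless a library is named.

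The most abundant nuclear genes of the gland were genes of steroid synthesis. Cyp21a1, the steroid 21-hydroxylase, had the highest mean of nuclear genes (ENSMUSG00000024365.9, chromosome 17, 34801348 to 34804561 of mm10) at 21047 ± 9936 CPM, followed by Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, at 20044 ± 260 CPM. In replicate 1 Cyp11a1 led, at 20228 CPM against 14022 for Cyp21a1. Cyp11b1, the 11-beta-hydroxylase of glucocorticoid synthesis, stood at 13717 ± 3103 CPM. Star, which moves cholesterol into mitochondria, reached 9632 ± 345 CPM, and Hsd3b1 reached 7636 ± 542 CPM. The 21 genes of the steroidogenesis list together held 82396 ± 12841 CPM, and 20 of them were detected.

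Among the other members, Akr1b7 stood at 2789 ± 188 CPM. The electron carriers of the mitochondrial enzymes followed, with Fdx1 at 1494 ± 580 CPM and Fdxr at 1233 ± 117 CPM. Nr5a1, the transcription factor of steroidogenic cells, stood at 1162 ± 76.1 CPM, and Cyp11b2, the aldosterone synthase, at 964.6 ± 171 CPM. Mrap, the partner of the corticotropin receptor, stood at 832.9 ± 74.1 CPM and the receptor Mc2r at 82.7 ± 1.20 CPM. Tspo, Gramd1b, Por, Cyb5a and Hsd11b1 had 454.6 ± 49.3, 374.0 ± 107, 351.2 ± 74.5, 300.7 ± 90.4 and 135.6 ± 30.5 CPM. Hsd3b6 and Nr0b1 had 85.0 ± 9.17 and 53.4 ± 5.17 CPM. Reads of near-identical relatives, such as Cyp21a1 and its pseudogene, Cyp11b1 and Cyp11b2, Hsd3b1 and Hsd3b6 or Hba-a1 and Hba-a2, may be assigned to the wrong member. Srd5a1 had 5 and 4 reads, and Hsd11b2 had 1 read in each library.

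Some genes of the zones and of cholesterol supply were also abundant. Detected were 11 of 17 zona glomerulosa, 7 of 7 zona fasciculata, 2 of 3 X-zone and 28 of 29 cholesterol supply genes. Of the zona fasciculata list, which shares Cyp11b1, Hsd3b1 and Akr1b7 with steroidogenesis, Abcb1b stood at 3385 ± 1194 CPM. Of the zona glomerulosa list, the potassium channel gene Kcnk3 stood at 2342 ± 1725 CPM, Wnt4 at 320.8 ± 65.5 CPM and Dab2 at 170.5 ± 150 CPM. Akr1c18, a marker of the X-zone, had 4840 ± 1767 CPM, with Pik3c2g at 112.9 ± 55.5 CPM and Thrb at 7.78 ± 5.37 CPM. By mean CPM, cholesterol supply was led by the lipoprotein receptor Scarb1 at 2912 ± 218 and Hmgcs1 at 1691 ± 1075 CPM. Fdps at 827.0 ± 224 and Insig1 at 795.6 ± 256 CPM followed. In replicate 2 Soat1 (949.0 CPM) exceeded Hmgcs1 (931.1), and Dhcr7 (859.4) exceeded Fdps (668.5) and Insig1 (614.7).

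Chromaffin genes of the medulla summed to 11245 ± 3782 CPM, against 82396 for steroidogenesis. Chgb and Chga, which encode granins of secretory granules, stood at 3847 ± 2126 and 3499 ± 1286 CPM. Th, the rate-limiting enzyme of catecholamine synthesis, stood at 1339 ± 44.9 CPM and Scg2 at 998.4 ± 70.8 CPM. The remaining genes among the 20 most abundant were Acly, Adh1, Car3, Hspa8, Ctsb, Gm15459, Hsp90ab1, Atp5b, Fads2, Hspd1 and Ctsd, between 3044 CPM for Ctsd and 5020 CPM for Acly. These 20 genes held 11.8% and 13.9% of reads.

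**Figure D1:**
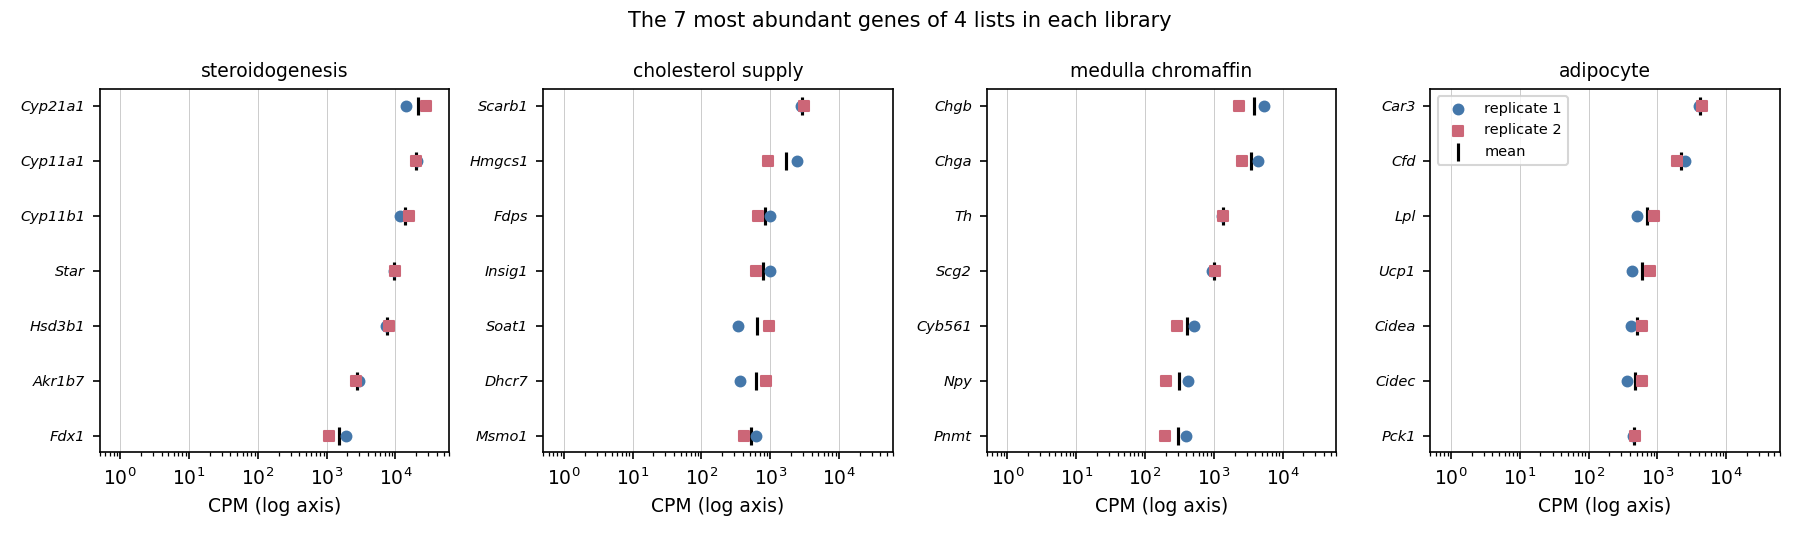
CPM on a log axis of the 7 most abundant genes of 4 lists, with replicate 1 as circles, replicate 2 as squares and the mean as a bar. Cyp21a1 leads steroidogenesis at a mean of 21047 CPM, and Chgb leads the medulla list at 3847 CPM.

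Markers of other cell types showed what else the dissected glands held. Adipocyte genes summed to 10156 ± 703 CPM, led by Car3 at 4226 ± 255, Cfd at 2195 ± 403, Lpl at 699.5 ± 285 and Ucp1 at 598.5 ± 240 CPM. Macrophage and antigen presentation genes summed to 1160 ± 44.9 CPM, with Cd74 at 349.0 ± 41.0, Lyz2 at 219.0 ± 14.2, H2-Ab1 at 167.4 ± 42.7 and H2-Eb1 at 76.9 ± 4.66 CPM. Red blood cell genes summed to 962.1 ± 292 CPM, with Hba-a1 at 472.6 ± 119.7, Hbb-bs at 280.2 ± 121, Hba-a2 at 126.6 ± 52.5 and Hbb-bt at 56.0 ± 14.4 CPM. Endothelial genes summed to 815.8 ± 157 CPM, led by Plvap at 348.9 ± 94.6, Eng at 145.1 ± 78.9, Tie1 at 65.6 ± 11.2 and Egfl7 at 52.2 ± 9.15 CPM. Capsule and fibroblast genes summed to 659.4 ± 122 CPM, with Col3a1 at 204.4 ± 92.1, Dcn at 147.5 ± 10.9, Fbln1 at 71.5 ± 8.68 and Col1a1 at 44.6 ± 1.21 CPM.

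Lymphocyte, kidney and Schwann cell lists had 1 detected gene each, namely Ighm, Cyp4b1 and S100b. Ighm, Lck, Cd4 and Cd79a led the lymphocyte list at 30.5 ± 3.69, 1.65 ± 2.34, 1.41 ± 0.822 and 0.995 ± 1.41 CPM. Cyp4b1, Napsa, Aqp2 and Nphs1 led the kidney list at 59.8 ± 16.7, 4.30 ± 3.27, 2.65 ± 0.932 and 0.995 ± 1.41 CPM. Of the Schwann and sustentacular list, S100b, Mbp and Sox10 had 14.6 ± 3.84, 8.02 ± 8.53 and 0.413 ± 0.585 CPM. Xist had 33 reads in replicate 1 and 6 in replicate 2, while the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 reads in both.

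Immediate early and stress genes summed to 3350 ± 1655 CPM, led by Hspa1b at 909.8 ± 643, Jund at 767.3 ± 293, Nr4a1 at 540.7 ± 544 and Jun at 436.2 ± 124 CPM. In replicate 1 the order was Jund, Jun, Hspa1b and Nr4a1, and Hspa1b led through replicate 2 (1365 against 454.8 CPM). Glucocorticoid target genes summed to 1212 ± 32.9 CPM, with Pdk4 at 321.9 ± 76.4, Tsc22d3 at 263.9 ± 24.3, Sgk1 at 145.4 ± 20.0 and Mt1 at 135.0 ± 55.8 CPM. Circadian clock genes summed to 519.0 ± 93.2 CPM, led by Nfil3 at 88.2 ± 16.0, Arntl at 83.4 ± 11.5, Dbp at 73.9 ± 10.9 and Nr1d1 at 65.0 ± 20.6 CPM. Antioxidant genes summed to 7418 ± 1061 CPM, with Prdx1 at 1364 ± 168, Gpx3 at 1034 ± 893, Prdx3 at 804.0 ± 81.2 and Txn2 at 761.8 ± 70.6 CPM. Imprinted genes summed to 4473 ± 393 CPM, led by Gnas at 1706 ± 297, Cdkn1c at 1587 ± 39.6, Dlk1 at 388.0 ± 92.7 and Meg3 at 224.6 ± 10.95 CPM. Gnas led through replicate 2, and in replicate 1 Cdkn1c was higher. Cell cycle genes summed to 258.1 ± 72.4 CPM, with Mcm6 at 66.5 ± 18.1, Mcm2 at 61.5 ± 19.4, Pcna at 53.8 ± 19.8 and Mcm5 at 28.3 ± 9.08 CPM. The mitochondrially encoded genes mt-Co1, mt-Cytb, mt-Nd2 and mt-Nd1 had 222, 101, 91 and 29 reads in replicate 1 and 110, 22, 21 and 27 in replicate 2.

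In all, 9942 genes were detected, of which 9553 were protein coding. Replicate 1 had 16123 genes with a read and replicate 2 had 13619. Across 16910 genes the libraries correlated with a Pearson's r of 0.912 and a Spearman's rho of 0.903 on the log2(CPM + 1) scale. Genes are not independent replicates, so no p-value is given.

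Single genes differed between the 2 libraries beyond counting error. Cyp21a1 was higher in replicate 2, at 28073 against 14022 CPM (log2 ratio 1.00, SE 0.016), while Cyp11a1 had a log2 ratio of -0.03 (Fisher's exact test, adjusted p = 0.320). Removing the trend with length and GC content gave Cyp21a1 a log2 ratio of 0.92, below the 2-fold threshold. Malat1, a nuclear long noncoding RNA (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), had 3550 reads in replicate 1 and 23 in replicate 2, a 64.1-fold difference. Srrm2 and Phip had 140 and 119 reads in replicate 1 and 1 read each in replicate 2, ratios of 58.2 (95% interval 10.3 to 2314) and 49.5 (8.71 to 1970). AC154200.1, Spata21, Patl2, Zfp839, Gm49450, Gm37376 and F11r had 0 reads in replicate 2. They were between at least 3.46-fold (F11r) and at least 15.9-fold (AC154200.1) lower there. Gm37376 (5801941 to 5802393) lies within Malat1 on the opposite strand. With annotated transcripts alone Zfp839 had a log2 ratio of -3.47 and missed the adjusted p. Phip, AC154200.1, Spata21, Patl2, Gm49450 and F11r had no reads in annotated transcripts, so that setting could not test them.

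Among genes higher in replicate 2, Gm49027 and Dhx35 had 0 reads in replicate 1 and were at least 9.62-fold and at least 8.02-fold higher. Myadm had 3 and 44 reads, a ratio of 35.3 (95% interval 11.3 to 178). Ppt2 had 5 and 38 reads, an 18.3-fold difference. Patl1, Atp1b2, Sp2, Raly, Phospho1 and Irf2 had 1 or 2 reads in replicate 1 and 9 to 18 in replicate 2, with ratios between 14.4 (3.21 to 133) for Irf2 and 26.5 (3.85 to 1139) for Patl1. Gm49027 and Sp2 had no reads in annotated transcripts, so their differences rest on reads outside them. Of 10170 genes tested, 971 were called, 606 higher and 365 lower in replicate 2. Fisher's exact test here compares 2 libraries, not conditions, and with 1 library a side the difference has no replicate check. Without the 2-fold minimum the count was 1823.

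Calls were unevenly spread over transcript length and GC content. Of genes with at least 100 reads, those with a main transcript under 1000 bases had a median log2 ratio of -0.55, with 1 called higher and 50 lower in replicate 2, and those over 5000 bases had a median of -0.28, with 8 higher and 32 lower. Genes over 54% GC had 89 higher and 38 lower.

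**Figure D2:**
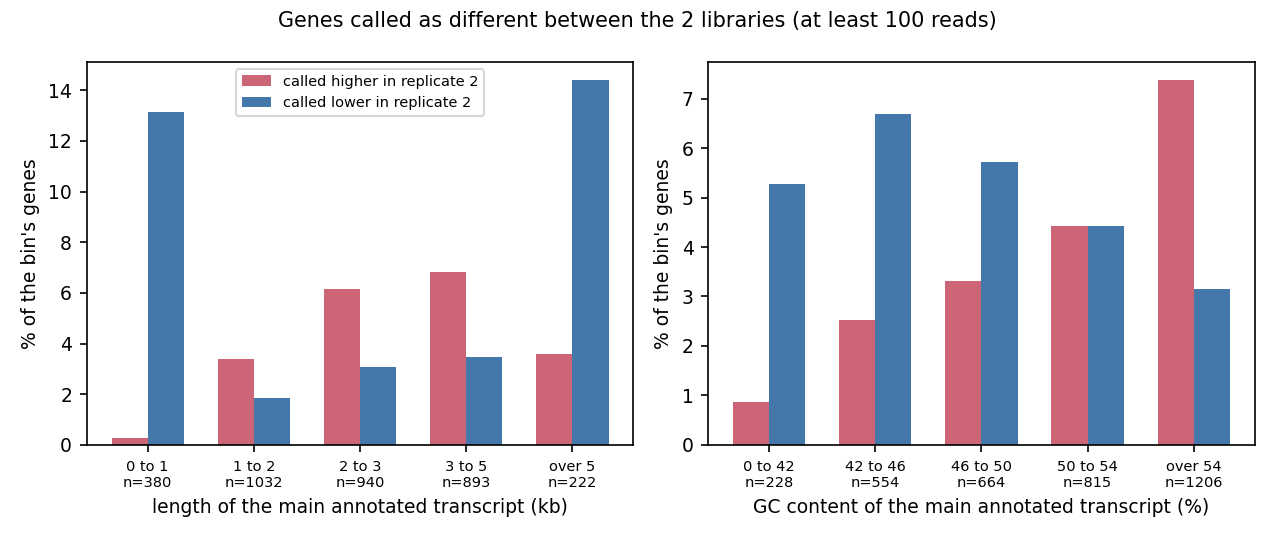
Percent of genes called higher or lower in replicate 2 by length and by GC content of the main annotated transcript, for genes with at least 100 reads. Under 1000 bases, 1 of 380 genes was called higher and 50 lower.

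Hmgcs1 and Lss, which encode enzymes of cholesterol synthesis, and the granin gene Chgb of chromaffin cells were lower in replicate 2, while Dhcr7 of cholesterol synthesis and Kcnk3 and Dab2 of the zona glomerulosa were higher. Cholesterol supply had a median log2 ratio of -0.40 over 29 genes, at percentile 0.300 of random lists, with 6 genes called higher and 5 lower in replicate 2. The higher genes were Lipa (1.82), Srebf2 (1.84), Soat1 (1.46), Dhcr7 (1.23), Lipe (1.05) and Nsdhl (1.01), and the lower ones included Hmgcs1 (-1.39), Lss (-1.24), Hsd17b7 (-1.12) and Stard4 (-2.93). With annotated transcripts alone Hsd17b7 had a log2 ratio of 0.011, so its call rests on reads outside them. It also lost its call without the genomic class (-0.19) and with the trend in length and GC content removed (-0.93). Lipe fell below 2-fold with the trend in length and GC content removed (0.55) and after thinning of the deeper library (0.96). Nsdhl did so after thinning (0.89) and with annotated transcripts alone (0.98). Without the read minimum Nsdhl stayed at 1.01 but missed the adjusted p. Stard4 kept a difference of over 2-fold but missed the adjusted p after thinning (-2.81) and with annotated transcripts alone (-2.53). The X-zone list had a median of -1.03 over 3 genes, at percentile 1.16. This median is the value of Pik3c2g, which was called lower. Akr1c18 stood at -0.76, and Thrb at -1.27 (SE 0.99) with 14 reads in replicate 1 and 2 in replicate 2. Pik3c2g lost its call after thinning (-0.87) and with the trend removed (-0.86). Medulla genes had a median of -0.32 over 26 genes, at percentile 4.36, with Chgb (-1.19), Npy (-1.07) and Pnmt (-1.03) called lower and Th at 0.07. Npy lost its call with the trend removed (-0.55), and Pnmt after thinning (-0.98) and without the genomic class (-0.99).

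Zona glomerulosa genes had a median of 0.21 over 12 genes, at percentile 94.2, with Kcnk3 (1.67), Dab2 (2.10), Agtr1a (1.92) and Lef1 (1.88) called higher in replicate 2 and Cyp11b2 at -0.36 and Wnt4 at -0.42. Steroidogenesis had a median of 0.07, at percentile 81.4, with Cyp21a1 as its called gene. The stress genes Nr4a1 (2.56), Hspa1a (1.89) and Hspa1b (1.59) were called higher, and their list had a median of -0.03, at percentile 53.1. With at least 50 reads required that median was 0.79 over 8 genes, at percentile 99.9, and with annotated transcripts alone 0.32, at 94.4. Of the antioxidant list (percentile 39.0), Gpx3 (2.05) and Cat (1.11) were called higher. The remaining called genes of the lists were Eng (1.17) of endothelium (68.3), Errfi1 (1.29) of glucocorticoid targets (26.5), Per2 (1.41) and Cry2 (1.31) of the clock (90.7), Mest (1.99) of imprinted genes (92.1), and Col1a2 (-1.90) and Mgp (-1.67) of capsule and fibroblast (49.5), with list percentiles in parentheses after list names. Eng fell below 2-fold after thinning (0.98) and with the trend removed (0.86), and Errfi1 after thinning (0.92). Lef1 (1.16), Col1a2 (-1.67) and Per2 (1.27) stayed over 2-fold after thinning, as did Mgp (-1.16) and Per2 (1.14) with the trend removed, but missed the adjusted p there. Zona fasciculata, macrophage, red blood cell, adipocyte and cell cycle genes had 0 calls, at percentiles 67.8, 36.8, 6.08, 83.5 and 9.06. At any fold, 13 steroidogenesis, 21 cholesterol supply, 7 medulla and 6 zona glomerulosa genes passed with p adjusted over the list alone, against 11, 20, 6 and 6 over all genes. For the X-zone, zona fasciculata, red blood cell and adipocyte lists these were 2, 6, 4 and 7 against 2, 4, 3 and 6. For immediate early, glucocorticoid target, clock, imprinted and antioxidant genes they were 6, 7, 2, 5 and 8 against 5, 4, 2, 4 and 7. Capsule, endothelial, macrophage and cell cycle genes had 3, 2, 0 and 0 against 3, 2, 1 and 0. Of 17 lists 2 lay outside the central 95% of random lists, against 0.85 by chance. With at least 50 reads required it was 6 of 16, with cholesterol supply, medulla and red blood cell genes below and zona glomerulosa, immediate early and imprinted genes above. With that minimum, and with annotated transcripts alone, the X-zone had too few genes to be tested.

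List medians also moved under other alternatives. Against lists matched on length and GC content zona glomerulosa stood at percentile 73.5, while cell cycle (1.08), imprinted (97.9), medulla (0.160), X-zone (0.115) and cholesterol supply genes (0.355) lay outside the central 95%. With the trend removed the median turned to 0.033 for red blood cell genes (percentile 56.3), 0.13 for antioxidant genes (85.3) and 0.047 for capsule and fibroblast genes (52.7). That of glucocorticoid targets turned from -0.18 to 0.15 (85.0) with at least 50 reads, and that of zona fasciculata from 0.039 to -0.21 (29.4) with annotated transcripts alone.

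**Figure D3:**
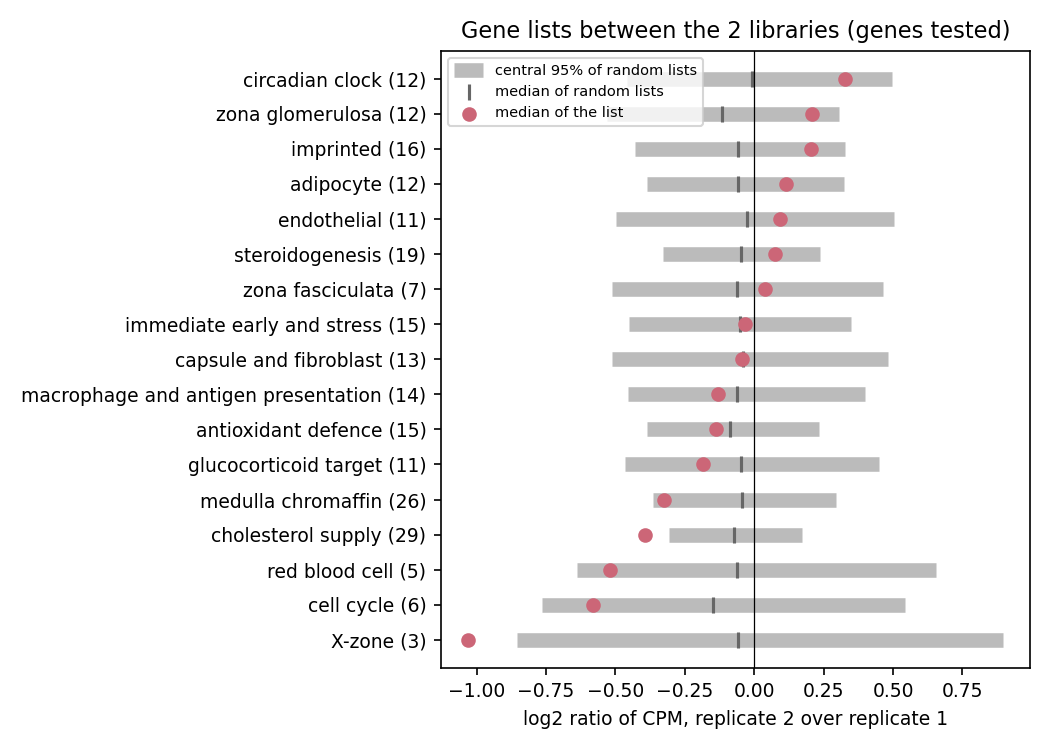
Median log2 ratio of CPM, replicate 2 over replicate 1, of 17 gene lists (points), with the central 95% of 10000 random lists matched on expression (grey bars) and their median (ticks); the number of tested genes follows each name. Cholesterol supply at -0.40 and the X-zone at -1.03 lie outside their bars.

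Annotated transcripts carried most reads of annotated genes, 76.5% (95% interval 76.5 to 76.6) in replicate 1 and 81.8% (81.7 to 81.9) in replicate 2. Incomplete splice matches held 11.6% and 7.08%, and genomic reads 4.66% and 2.46%. Models new in catalog held 4.13% and 4.88%, and those new not in catalog 3.09% and 3.74%. Of Cyp11a1, genomic reads made up 25.3% ± 6.59. All 33 and 6 reads of Xist were genomic. Incomplete reads were a larger share in long genes, at 14.3% ± 5.27 of reads for genes over 4 kb and 3.80% ± 0.734 for genes under 1 kb by the longest annotated transcript. By the median length of annotated transcripts these were 17.7% ± 5.75 and 8.23% ± 2.93. By the longest, genes over 4 kb stood at 18.0% in replicate 1 and 10.6% in replicate 2.

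**Figure D4:**
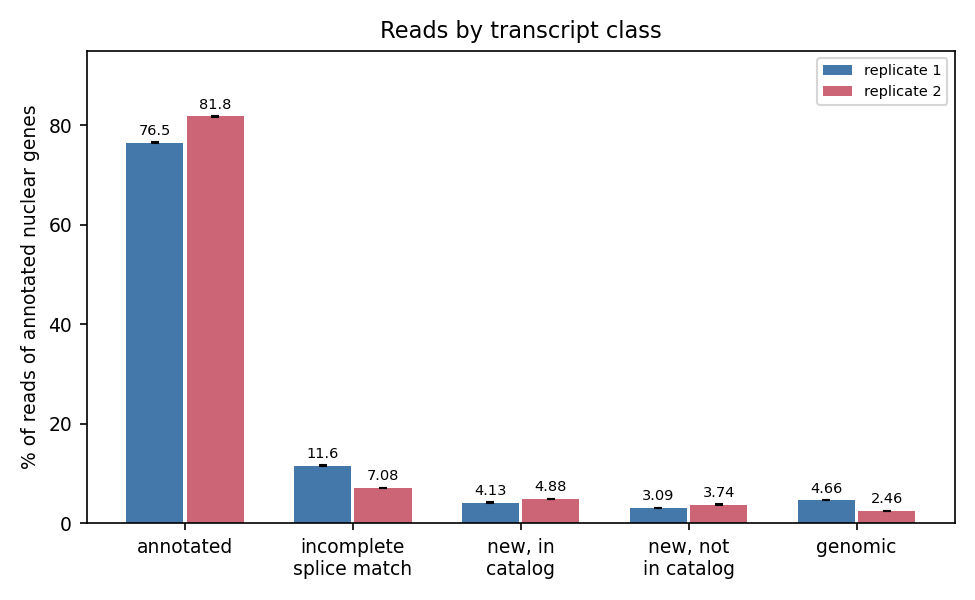
Share of the reads of annotated nuclear genes in each transcript class in each library, with exact 95% intervals as error bars. Annotated transcripts hold 76.5% in replicate 1 and 81.8% in replicate 2.

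In both libraries, several abundant genes used a transcript whose chain of introns is absent from the annotation. For Oaz1 and Oaz2 the only difference in introns from the closest annotated transcript was an annotated gap of 1 base. They count as new for that reason alone, so no other form of splicing is shown for these 2 genes. Oaz1, which encodes ornithine decarboxylase antizyme, had 1784 and 737 reads in a transcript that lacked an annotated gap of 1 base (chromosome 10, position 80828295 of mm10), 95.7% ± 0.362 of its reads. Oaz2 lacked a like gap of 1 base (chromosome 9, position 65686272) in 89.4% ± 0.714 of its reads. Phb2 carried 1 annotated intron (chromosome 6, 124716031 to 124716605) in 93.9% ± 5.48 of its reads. The closest annotated transcript has 2 there (124716031 to 124716424 and 124716431 to 124716605), around an exon of up to 30 bases. Cct6a and Chmp1a held 89.2% ± 1.95 and 84.2% ± 1.26 in a new transcript, Idh3g 71.0% ± 4.16 and Ctbp1 63.7% ± 1.80. That of Idh3g also lacked an annotated exon of up to 30 bases and had a donor outside the annotation. That of Ctbp1 had an annotated intron of 420 bases where the closest annotated transcript has 1 of 423. Cdkn1c, a cell cycle inhibitor, had new transcripts with 23.1% ± 1.96 and 14.4% ± 1.36 of its reads.

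In Cyp11b1, a new transcript with an acceptor outside the annotation held 1.18% ± 0.264 of reads, its intron spanning 74835888 to 74836232 of chromosome 15 where the annotated one spans 74835867 to 74836232. In all, 1622 new transcripts of 1100 genes were shared, with 37.6% and 38.6% of the reads in new transcripts. Of those with at least 3 reads in replicate 2, 88.3% were also seen in replicate 1, against 22.2% of those with 1 read, and 69.4% of those with at least 3 reads in replicate 1 were seen in the shallower replicate 2. Of the 1622, 21.1% differed from an annotated transcript by 1 splice site moved by up to 30 bases. New means absent from the annotation of mm10, and whether sequence differences of the hybrid from mm10 moved splice sites was not tested. The count depends on the minimum, with 7673 at 1 read and 343 at 10 reads.

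Most genes used 1 main transcript. The median main share was 93.0% over 1887 genes, and the main transcript was new in 51. Of these 51, 10 lacked an annotated exon of up to 30 bases and 9 had 1 splice site moved by up to 30 bases. A further 2, Oaz1 and Oaz2, read through an annotated gap, which was of 1 base in each. The 16 steroidogenesis genes that passed had a median of 94.4%, with Cyp11b1 at 96.5% ± 0.256 and Star at 98.3% ± 0.384. The lowest were Hsd11b1 at 47.6% ± 4.31, Nr5a1 at 63.1% ± 2.05, Hsd3b1 at 74.1% ± 5.33 and Gramd1b at 74.1% ± 2.07. Shares leave out incomplete and genomic reads. That of Hsd3b1 rests on 853 and 339 of its 8772 and 4031 reads, and that of Nr5a1 on 524 and 500 of 1340 and 611. A second coding transcript of Hsd11b1 held 45.9% ± 5.82. Medulla genes had a median of 96.0%, with Cyb561 at 54.7% ± 3.96 in a new transcript, Scg2 at 55.7% ± 4.02, Th at 87.5% ± 4.28 and Chga at 96.0% ± 0.756. Cholesterol supply had a median of 92.1%, with Lipe at 50.3% ± 6.77, Hmgcs1 at 58.0% ± 1.03, Fdps at 72.6% ± 5.01 and Lipa at 88.3% ± 0.819. Imprinted genes had a median of 56.6% over 5 genes, with Meg3 at 24.0% ± 12.8, Cdkn1c at 33.0% ± 1.85, Gnas at 56.6% ± 1.16 and Dlk1 at 69.8% ± 5.46.

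The main transcript differed between the libraries in few genes. Eprs, a transfer RNA synthetase (ENSMUSG00000026615.14), had 90.4% of its reads in annotated and new spliced transcripts in the retained-intron transcript Eprs-204 in replicate 1 and 9.90% in replicate 2, where the coding Eprs-201 held 83.2% (Fisher's exact test, adjusted p = 5.18e-60). Atf4, a stress response factor, had 47.8% in the retained-intron Atf4-203 in replicate 1 and 3.61% in replicate 2. Eif2s2 and Ddx24 had 20.9% and 21.6% in retained-intron transcripts in replicate 1 and 0 of 179 and 0 of 113 reads in replicate 2. The main transcript shares of Araf, Suds3, Ndufv3, Slc25a25, Acsl5 and Rps15 differed by 44.1, -39.1, -25.6, 24.6, -23.3 and -19.2 percentage points, replicate 2 minus replicate 1. The difference of Rps15 was -6.06 with all classes in the denominator, and that of Acsl5 was 0 with annotated transcripts alone. Calls were made for 14 genes and 19 passed the adjusted p at any difference. Fisher's exact test again compares 2 libraries, and with all classes in the denominator 356 genes were called.

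Spike-in RNA, added in known mixtures, took 1.36% (95% interval 1.34 to 1.38) of reads in replicate 1 and 0.920% (0.894 to 0.946) in replicate 2. Of 96 ERCC transcripts in the models, 48 and 34 had a read. ERCC-00002 had 5740 and 1516 reads and ERCC-00130 had 3534 and 874. Over the 29 spike-ins with at least 10 reads, the SD of the log2 ratio was 0.91.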

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

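Removal of the trends in length and GC content, random lists matched on both and the spike-in tests of orientation were chosen after seeing the result, as were the 3 patterns. Cholesterol supply was picked because it had the lowest percentile of 17 lists. No biological explanation was tested, since the design gives none. Reads in new genes were part of the files but of no planned comparison. New antisense genes held 3.41% of reads in replicate 1 and 2.12% in replicate 2, and new intergenic genes held 0.494% and 0.318%.

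Genes called as different between the libraries were uneven in transcript length and GC content. With the trend in length removed 79.2% of the 971 called genes were still called, and with that in GC content removed 82.4%. With annotated transcripts only it was 73.5%. None of the 3 alone, as removed here, accounts for most calls. Removing a trend takes away only the median shift of genes of like length or GC content. By length that median ran from -0.55 to -0.06 in genes with at least 100 reads, while a call needs a 2-fold difference. Effects that vary between genes of like length or GC content were therefore out of reach of this test. With length and GC content removed together 68.9% remained.

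The cholesterol supply list lay low in replicate 2. Against random lists matched also on length and GC content its percentile was 0.355, and with annotated transcripts only 1.33. Neither explanation fits. An extreme percentile is more likely for a list picked as the lowest of 17.

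Reads of new antisense genes may be sense reads taken in the wrong orientation. The ratio of the antisense share of spike-ins to that of the tissue was 0.314 (95% interval 0.271 to 0.361) in replicate 1 and 0.530 (0.400 to 0.689) in replicate 2. As the whole cause this would need a ratio of 1 if spike-ins and tissue RNA were misread at the same rate, which was not tested. The higher upper bound, 0.689, lies below 1, which argues against wrong orientation as the whole cause under that assumption only. Antisense reads rose with sense reads across genes with a Spearman's rho of 0.345 and 0.203. Wrong orientation as a part of the cause stays open, since the bound of 0.333 set for both libraries was passed in replicate 2 and not in replicate 1, and neither lay under 0.1. The abundance of sense transcripts stays open too, since rho lay between the bounds of 0.1 and 0.5 in both.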

How the results depend on the processing

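Removing the trend with transcript length and GC content and matching random lists on both were chosen after seeing the result. The other alternatives were fixed before. A count was taken as unmoved within 1.5-fold of its main value, and a correlation within 0.05. Expression levels and shares were taken as unmoved within the SD of the 2 libraries. By this rule, 39 alternatives to the central results left the result unmoved and 21 moved it. Unmoved counts still ran from 6653 to 12832 for the 9942 detected genes and from 648 to 1132 for the 971 called genes. The cause of a move was not tested unless the change is one of definition.

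Without the 2-fold minimum the number of genes called between the libraries rose from 971 to 1823. The number of lists outside the central 95% of random lists was 2, and it became 6 with at least 50 reads over both libraries and 5 with random lists matched on expression, length and GC content. Pearson's r fell from 0.912 to 0.802 with 0.1 added to CPM. Shared new transcripts, 1622 at first, numbered 7673 with at least 1 read in both libraries, 844 with 5 and 343 with 10. They numbered 1059 for the class new in catalog, 418 for the class new not in catalog and 590 with at least 10% of the reads of the gene. Within 1 library they ranged from 2329 to 4764, where no match is asked for.

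The median main transcript share, 93.0%, became 82.9% with all classes in the denominator and 99.1% with annotated transcripts only. It became 90.8% with at least 20 reads and 96.0% with at least 200 reads in each library, and 93.2% to 93.3% with 1 replicate left out. The number of genes with a called difference in share, 14, became 356 with all classes, 24 with at least 20 reads, 2 with at least 200 reads and 8 with a difference of at least 20 percentage points. For expression and class shares, leaving out 1 of 2 libraries cannot move the mean beyond the spread of the 2 by construction.

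The log2 ratio of 23 gene results changed sign. With annotated transcripts only it became -0.065 for Th, 0.18 for Meg3, -0.047 for Atp5b, -0.25 for Hsd3b1, -0.0030 for Star, 0.093 for Cyp11a1, 0.15 for Tie1, -0.017 for Cdkn1c and 0.011 for Hsd17b7. Hsd17b7 was the only called gene among these. Without the genomic class it became 0.068 for Meg3, -0.0010 for Atp5b, 0.12 for Cyp11a1 and -0.20 for Mc2r. After thinning of the deeper library it became -0.054 for Dcn and -0.019 for Atp5b. With the trend removed it became -0.26 for Nr5a1, -0.070 for Cdkn1c, -0.15 for Scarb1, 0.053 for Tspo, 0.027 for Akr1b7, 0.036 for Lyz2, 0.033 for Hba-a1 and 0.12 for Hbb-bt. Of 368 alternatives in which a called gene was still tested, 343 were the same, 24 weaker and 1 reversed. Alternatives that left a gene untested are not counted there. Both other scalings are counted, though their factors lay between 0.994 and 1.006 and left all 135 named genes the same. The minimum of 50 reads, which keeps the counts of a gene, left all 113 it tested the same. The total of 343 therefore includes settings that could hardly change a call. Of all 971 calls, 64.2% were kept with at least 50 reads required and 65.9% after thinning.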

Other observations

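The genes named here, the comparison of sequence words, the antisense counts per gene, the share of retained-intron transcripts, removal of the trend and the random lists matched on length and GC content were chosen after seeing the result. The chaperone gene Hspa8 and its processed pseudogene Gm15459 had nearly the same reads. Gm15459 had 3733 reads in replicate 1 and 2011 in replicate 2, against 3830 and 2058 for Hspa8. Of the 31-base words of Gm15459, 91.9% occur in transcripts of Hspa8. How reads that fit both were assigned is not given in the sources used here.

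Actb, which encodes beta-actin, had 2078 antisense and 1255 sense reads in replicate 1. Ywhaz had 469 antisense and 215 sense reads there. In replicate 2, Neat1 had 112 antisense and 30 sense reads, and Sept2 had 127 and 17. Annotated retained-intron transcripts held 1.07% of annotated reads in replicate 1 and 0.705% in replicate 2.

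Medulla genes stood at percentile 4.36 of random lists. They stood at 5.59 with 1 read added, 4.06 with either other scaling, 1.90 with annotated transcripts only and 0 with at least 50 reads required. They stood at 0.160 with lists matched on length and GC content and at 0 with the trend removed.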
